A study of Homo sapiens with 12 samples.

How the data were processed

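RNA from SRA01/04 cells, an immortalised human lens epithelial cell line, was measured by sequencing after 24 hours of treatment. Total RNA was purified with a silica column kit and made into stranded libraries, per the labels' protocols. The deposited table holds raw read counts per gene symbol for 12 libraries, with a gene length for each symbol; the authors' values are whole numbers whose totals differ between libraries. The reference genome was hg38 and the read aligner Bowtie, per the submitters' processing notes. The version of the aligner, its settings, the tool and strand setting used for counting, the annotation, the doses, whether asparagine was added before, with or after 1,2-DHN, and whether the replicates were separate cultures are not given in the sources used here. Reads that match several near-identical genes, or exons of overlapping genes, can be lost or split in ways that such a table does not show.

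The table lists 60641 symbols, none duplicated. Of these, 55381 (91.3%) matched the symbol of 1 gene in GENCODE release 29 (GRCh38), and 39502 of the matched symbols (71.3%) had a length equal to the union of that gene's exons, so the authors' annotation was not identical to it. Coordinates in the report come from GENCODE release 29 by symbol, 1-based. Another 3 symbols are calendar dates and were kept as they are. Library names and groups were taken from the labels; there were 4 groups with 3 libraries each.

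Total counts ran from 12381071 in DHN 1 to 27526206 in DHN-A 1. Genes were kept for testing when edgeR's filter on low counts (filterByExpr with the 4 groups) passed them. This left 17889 tested genes and 42752 untested symbols, of which 17451 had no count in any library. Library sizes were scaled with trimmed mean of M values factors. A quasi-likelihood model with 1 mean per group (edgeR 4.0.16, R 4.3.3, robust) was fitted to all 12 libraries, so that every comparison shares 1 estimate of the spread. Fold changes are on the log2 scale, with standard errors derived from each fold change and its quasi-likelihood test. For large changes these errors are approximate and may be too small. For the gene HSPA6 they were 0.067 in DHN against NC and 0.11 in DHN-A against NC-A. Those comparisons share no library, yet the interaction, which is their difference, had 0.18, more than their errors combine to. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. There were 6 comparisons, 5 between pairs of groups and the interaction, which is the change from NC-A to DHN-A minus the change from NC to DHN. Levels are given as CPM, computed here from the deposited counts and the scaled library sizes.

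A set of 30 gene lists (668 memberships, 609 of them tested) was fixed before the data were examined, as were the tests, the comparisons and the rule for the genes that are named. Lists with at least 5 tested members, 28 in all, were tested against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Adjustment was over the 28 lists of a comparison. The same test with a correlation estimated from the residuals, and fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes, were alternatives. The rule for naming genes took those with the largest rises and falls among called genes with a mean of at least 50 counts and no overlap between the groups' replicates. There were up to 8 in each direction for the first 2 comparisons and up to 5 for the others, where the interaction had no overlap criterion. It added a fixed set of stress genes in every comparison and, for lists with a call, up to 4 members with the smallest p. Genes with placeholder names were left out, and some results that the rule selects are not reported here.

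The procedure was tested on simulated data for DHN against NC. Counts were drawn for 17889 genes, 200 of them changed, and 17487 genes passed the filter on low counts and were tested. The procedure called 77% of 1.5-fold changes and 84% of 2-fold changes, and 5.85% of its calls were unchanged genes. A target set for the 2-fold changes was missed and was lowered after the result. In a simulated comparison with no change it made 3 calls. A shifted list was called and 0 of 19 unshifted lists were. Genes were drawn independently, so this says nothing about false list calls where the genes of a list are correlated. For comparisons that share libraries, 20 simulated data sets with no change in the groups that are set against the shared libraries gave the correlation, covariance, share of opposite signs and overlap without an effect.

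Alternatives were relative log expression factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a minimum change of 2-fold, a fit with the replicate number as a block, a fit of only the groups compared, and each library left out in turn. Chosen after the data were seen were thinning of all libraries to 12381071 counts over all symbols, the total of the shallowest library, removal of a trend with GC content (96.1% of tested genes had a GC value), a test of 13310 protein-coding genes alone, and leaving NC-A 1 out of the shared fit. Figures were drawn with matplotlib 3.10.9.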

Results

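Gene expression was measured in 12 libraries of SRA01/04 cells to ask how asparagine changes the response of human lens epithelial cells to 1,2-DHN (1,2-dihydroxynaphthalene, a naphthalene metabolite that is oxidised to a quinone). The groups were cells given neither (NC), cells given asparagine (NC-A), cells given 1,2-DHN (DHN) and cells given both (DHN-A), with 3 libraries each at 24 hours; the order in which the 2 compounds were added is not given in the sources used here. The total counts of libraries 1, 2 and 3 were 16514049, 21151832 and 24225424 in NC and 13529028, 13785921 and 17478970 in NC-A. They were 12381071, 20832322 and 21318168 in DHN and 27526206, 25868418 and 23816595 in DHN-A. Replicates varied beyond counting noise by 4.60% (the square root of edgeR's common dispersion), and no pair looked like a repeat deposit of the same library, since the mean chi-square per gene of a pair was 1.84 to 4.98. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The first principal component (33.9% of variance) placed the DHN libraries between 38.5 and 42.4, while NC-A 1 lay at -65.1, away from NC-A 2 at -12.5 and NC-A 3 at -10.4. Mitochondrially encoded transcripts took 2.73% to 3.23% of the counts of each library. HSPA1A has the near-identical neighbour HSPA1B and HSPA6 the near-identical pseudogene HSPA7, so the counts of these genes are uncertain where reads could match both.

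**Figure D1:**
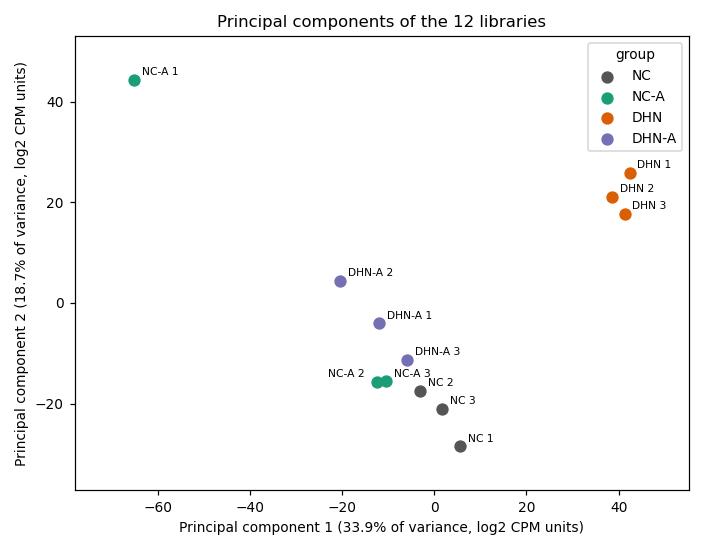
Principal components of log2 CPM over the tested genes, 1 point per library, coloured by group; the axes give the first (33.9% of variance) and second (18.7%) components. The 3 DHN libraries lie at 38.5 to 42.4 on the first component and NC-A 1 at -65.1.

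DHN against NC asked what 1,2-DHN did without added asparagine. Genes of protein folding stress were among the largest rises. HSPA6, an inducible HSP70 chaperone on chromosome 1 from 161524540 to 161526910 (GRCh38), went from 4.27 ± 0.476 to 503 ± 9.03 CPM (mean ± SD, n = 3), a log2 change of 6.86 ± 0.067 (± SE, as for all log2 changes). HSPA1A, another inducible HSP70 on chromosome 6 from 31815464 to 31817946, rose by 5.06 ± 0.12, and CRYAB, the small heat shock protein alpha B-crystallin of the lens on chromosome 11 from 111908565 to 111923722, by 3.87 ± 0.23. The level of CRYAB was low, with means of 0.704 CPM in NC, 1.10 in NC-A, 10.8 in DHN and 3.815 in DHN-A. HMOX1, the haem-degrading enzyme of the oxidative stress response on chromosome 22 from 35380361 to 35394214, rose from 32.2 ± 3.23 to 137 ± 4.88 CPM (2.08 ± 0.058). Genes of interferon signalling, hypoxia, mitosis and matrix fell, among them the interferon-induced GTPase MX1 on chromosome 21 from 41420304 to 41459214, by 1.26 ± 0.044.

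Among the heat shock genes 20 of 20 tested members rose (20 adjusted over the list alone), with a median log2 change of 0.85 (camera adjusted p = 1.35e-19). They included BAG3, an HSP70 cochaperone (1.51 ± 0.036), and HSPB1, the small heat shock protein HSP27 (1.27 ± 0.038). Of the targets of NRF2, the transcription factor of the electrophile response, 26 of 30 tested members rose (26 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 1.71e-13). NQO1, a quinone reductase on chromosome 16 from 69706996 to 69726951, rose by 1.05 ± 0.049, TXNRD1, thioredoxin reductase, by 0.92 ± 0.036, and FTL, the ferritin light chain, by 0.88 ± 0.037. Of the aryl hydrocarbon receptor targets 5 of 7 rose (5 adjusted over the list alone, camera adjusted p = 0.000944). NQO1 belongs to this list too, so the 2 list calls share a member. CYP1A1, a cytochrome P450 that oxidises polycyclic hydrocarbons, rose by 1.13 ± 0.25. Its level was low, at 1.39 ± 0.363 CPM in NC and 3.07 ± 0.472 in DHN (mean ± SD, n = 3). TIPARP, an ADP-ribosyltransferase, rose by 0.42 ± 0.046. AKR1B1, aldose reductase, was not called (edgeR adjusted p = 0.951, log2 change -0.0051 ± 0.049), and its sign turned without NC 3 (0.0033) or DHN 2 (0.0353).

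In the ATF4 and amino acid response list 24 of 34 tested members rose and 5 fell (25 and 5 adjusted over the list alone; camera adjusted p = 4.83e-09). SLC3A2, the heavy chain of amino acid exchangers, rose by 1.54 ± 0.041, SESN2, a stress-inducible sestrin, by 1.41 ± 0.049, and ATF4 itself by 0.66 ± 0.037. CHAC1, which degrades glutathione, rose by 1.67 ± 0.11, the pseudokinase TRIB3 by 1.08 ± 0.060, DDIT3 (CHOP) by 1.04 ± 0.094 and ASNS, asparagine synthetase, by 1.12 ± 0.20. The endoplasmic reticulum chaperones moved the other way: 3 of 23 rose and 16 fell (3 and 16 adjusted over the list alone; camera adjusted p = 0.00128, but adjusted p = 0.0804 with an estimated correlation). HSPA5, the luminal HSP70 BiP, fell by 0.55 ± 0.034 and the disulfide isomerase PDIA4 by 0.57 ± 0.034, while ERN1, the stress sensor IRE1, rose by 1.10 ± 0.073. Of the immediate early and AP-1 genes 16 of 23 rose and 4 fell (16 and 4 adjusted over the list alone; camera adjusted p = 4.42e-07, but adjusted p = 0.0611 with an estimated correlation), with FOSB at 3.89 ± 0.12, FOS at 3.02 ± 0.11, EGR1 at 2.38 ± 0.059 and ATF3 at 1.15 ± 0.041. Of the p53 targets 16 of 23 rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 1.68e-07), with the growth arrest genes GADD45A at 1.18 ± 0.042 and CDKN1A (p21) at 0.80 ± 0.040. Other large rises were those of ARC, an activity-regulated gene (6.05 ± 0.14), RASD1, a small GTPase (4.21 ± 0.16), and MYLIP, a ubiquitin ligase (3.84 ± 0.23).

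Of the interferon response genes 18 of 21 tested members fell (18 adjusted over the list alone; camera adjusted p = 2.15e-13), and OAS1, an antiviral oligoadenylate synthetase, fell by 1.21 ± 0.048. Of the hypoxia and glycolysis genes 3 of 23 rose and 16 fell (4 and 16 adjusted over the list alone; camera adjusted p = 2.73e-07). BNIP3, a mitophagy receptor, fell by 1.28 ± 0.040, LDHA, lactate dehydrogenase, by 1.13 ± 0.035, SLC2A1, the glucose transporter GLUT1, by 1.11 ± 0.040 and CA9, a carbonic anhydrase, by 1.88 ± 0.15. Of the mitosis genes 22 of 23 fell (22 adjusted over the list alone; camera adjusted p = 2.15e-13), with the kinesin KIF20A at -0.75 ± 0.044 and the kinase PLK1 at -0.67 ± 0.044. Of the matrix and epithelial-mesenchymal transition genes 4 of 26 rose and 16 fell (4 and 16 adjusted over the list alone; camera adjusted p = 2.36e-05). FN1, fibronectin, and COL1A1, a collagen I chain, fell by 0.82 ± 0.034 and 0.83 ± 0.035, whereas SNAI1, a transcription factor of that transition, rose by 3.31 ± 0.13. Other large falls were those of PPFIA4, a liprin (-2.20 ± 0.13), TNFSF10, the death ligand TRAIL (-1.99 ± 0.085), APLN, apelin (-1.93 ± 0.12), IDO1, a tryptophan-degrading enzyme (-1.81 ± 0.20), the guanylate-binding protein GBP4 (-1.64 ± 0.056), TENM2, a teneurin (-1.63 ± 0.044), and MMP13, a collagenase (-1.51 ± 0.23).

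Of 28 lens markers 10 were tested, of which 3 rose and 2 fell (3 and 2 adjusted over the list alone); the list was not called (camera adjusted p = 0.705), and its median of -0.049 and mean of 0.56 differ in sign. The highest change of the list was the 3.87 of CRYAB, a gene with a low level. Of the fibroblast markers, of which 3 are collagens of the matrix list, 6 of 8 fell (6 adjusted over the list alone; camera adjusted p = 0.000163), with COL6A3, a collagen VI chain, at -1.24 ± 0.042. Of 10 markers each of other cell types, 8 of fibroblasts, 4 of immune cells, 2 of keratinocytes and 5 of pigment cells had enough counts for a test. With 10 of 28 tested, the lens markers did not stand out from these. Of the immune cell markers 1 of 4 rose and 2 fell (1 and 2 adjusted over the list alone). Of the keratinocyte markers 1 of 2 rose (1 adjusted over the list alone), and of the pigment cell markers 1 of 5 (1 adjusted over the list alone).

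Across all genes, edgeR called 6919 of 17889 in DHN against NC, 3520 higher and 3399 lower, and 635 of them changed at least 2-fold. Of 28 lists camera called 17, of which 12 were also called with an estimated correlation. NC-A 1, which stands apart, enters this count only through the shared filter, scaling and estimate of spread. With it left out of the fit, filter and scaling were also rerun, and 7112 genes were called.

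DHN-A against DHN asked what asparagine did in cells given 1,2-DHN. Heat shock genes and NRF2 targets, which 1,2-DHN raised, were lower with asparagine. HSPA6 was at 11.4 ± 1.23 CPM in DHN-A against 503 ± 9.03 in DHN (mean ± SD, n = 3), a fall of 5.46 ± 0.056 on the log2 scale and 44-fold. HSPA1A fell by 3.44 ± 0.10, FOSB by 4.22 ± 0.12 and CRYAB by 1.49 ± 0.17. HMOX1 fell by 1.51 ± 0.054 to 48.1 ± 1.69 CPM. Genes of interferon signalling rose, with MX1 up by 1.10 ± 0.043, and the death ligand TNFSF10 rose by 1.47 ± 0.086.

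Of the heat shock genes 20 of 20 tested members fell (20 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 5.35e-21); BAG3 fell by 1.61 ± 0.036 and HSPB1 by 1.35 ± 0.038. Of the NRF2 targets 1 of 30 rose and 24 fell (1 and 24 adjusted over the list alone; camera adjusted p = 1.98e-11), with TXNRD1 at -0.66 ± 0.035, FTL at -0.61 ± 0.036 and NQO1 at -0.53 ± 0.046. Of the interferon response genes 13 of 21 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.00097), with OAS3 at 0.91 ± 0.037 and XAF1, an interferon-induced apoptosis factor, at 1.67 ± 0.12. These 3 lists were also called with an estimated correlation (adjusted p = 0.00131, 0.00117 and 0.0337). The 12 other lists that camera called were not. Among them, of the immediate early and AP-1 genes 3 of 23 rose and 16 fell (3 and 16 adjusted over the list alone; camera adjusted p = 2.17e-07), with FOS at -3.50 ± 0.12 and ATF3 at -1.11 ± 0.040 (adjusted p = 0.0757 with an estimated correlation). Of the mitosis genes 16 of 23 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 2.09e-06), with PLK1 at 0.55 ± 0.044 and KIF20A at 0.53 ± 0.044 (adjusted p = 0.0757 with an estimated correlation). Of the matrix genes 15 of 26 rose and 6 fell (16 and 6 adjusted over the list alone; camera adjusted p = 0.0072), with SNAI1 at -3.09 ± 0.12 and FN1 at 0.57 ± 0.034 (adjusted p = 0.0757 with an estimated correlation). Of the fibroblast markers 4 of 8 rose (4 adjusted over the list alone; camera adjusted p = 0.047, but adjusted p = 0.129 with an estimated correlation), and that call was also lost without DHN 2 (0.0564) or DHN-A 3 (0.0682) and with the replicate block (0.0621), in a range of 1.48e-06 to 0.129 over 10 alternatives.

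Not every change of DHN was opposed. Of the hypoxia and glycolysis genes, which as a list were lower in DHN than in NC, 3 of 23 rose and 12 fell (3 and 14 adjusted over the list alone; camera adjusted p = 0.000946, but adjusted p = 0.0757 with an estimated correlation). Of the 16 members called lower in DHN against NC, 7 were called lower again and 3 higher. ADM, the vasodilator adrenomedullin, had the opposed pattern: it was at 11.9 ± 1.43 CPM in NC, 42.3 ± 1.73 in DHN and 9.18 ± 0.362 in DHN-A (mean ± SD, n = 3), and fell by 2.21 ± 0.094 in DHN-A against DHN. PFKFB3, a regulator of glycolysis, was at 156 ± 4.77 CPM in NC and 156 ± 6.52 in DHN and fell by 0.49 ± 0.042. HSPA5 fell further, by 0.44 ± 0.034. In the ATF4 and amino acid response list 12 of 34 rose and 12 fell (13 and 12 adjusted over the list alone), and the list was not called (camera adjusted p = 0.523). SLC3A2 fell by 0.94 ± 0.039, ALDH1L2, a mitochondrial folate enzyme, rose by 0.95 ± 0.067, and ATF4 was at -0.068 ± 0.036 (edgeR adjusted p = 0.128, or 0.0340 after removal of a GC trend; 0.0340 to 0.572 over 16 alternatives). ASNS was at -0.058 ± 0.17 (edgeR adjusted p = 0.821), and without DHN-A 1 its sign turned, at 0.0012. Other large rises were those of IDO1 (1.76 ± 0.19), the sulfotransferase SULT1C2 (1.74 ± 0.14), ZP4, a zona pellucida gene (1.55 ± 0.23), MMP13 (1.47 ± 0.23) and ZMAT1, a zinc finger gene (1.46 ± 0.16). Other large falls were those of RASD1 (-3.62 ± 0.14), ARC (-3.52 ± 0.10) and MYLIP (-3.28 ± 0.21).

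Across all genes, edgeR called 7455 in DHN-A against DHN, 3743 higher and 3712 lower, 670 of them by at least 2-fold; with NC-A 1 out of the shared fit it called 7835. Of the 6919 genes called in DHN against NC, 6415 (92.7%) had the opposite sign in DHN-A against DHN. Unchanged groups set against the shared DHN libraries gave 58.3% (57.5 to 59.3 over 20 simulations). Of the 3520 genes higher in DHN, 2594 were called lower in DHN-A than in DHN, where independent lists would share 730. Of the 3399 lower in DHN, 2300 were called higher in DHN-A, against 711. The simulated overlaps (means of 0.35 and 0.20) do not measure what shared libraries add here, since the unchanged group had a mean of 0.95 calls. Across genes, which are not independent replicates, the changes had r = -0.724 (simulated -0.242) and a covariance of -0.195 (simulated -0.0355, a difference of -0.160). That covariance was -0.250 to -0.218 with 1 library left out, all beyond the reported value, and -1.04 with no filter on low counts; the simulation was not repeated in those settings. The independent overlap leaves out the shared libraries, so part of the excess may come from them.

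**Figure D2:**
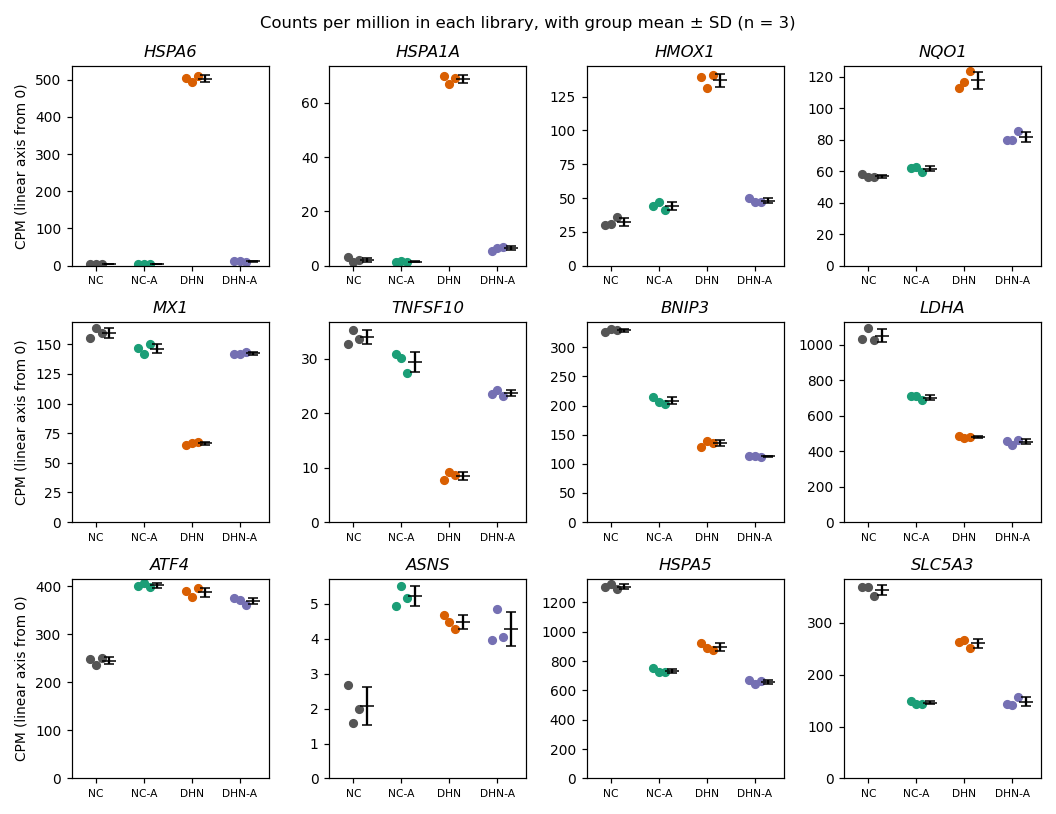
CPM (linear axes from 0) of 12 genes in each library, coloured by group, with the group mean and SD (n = 3) as black bars. HSPA6 stands at 503 in DHN and 11.4 in DHN-A, while SLC5A3 is lower in both groups given asparagine (146 and 148) than in NC (363).

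NC-A against NC asked what asparagine did on its own. Genes of the ATF4 and amino acid response rose, and the transporters SLC5A3 and SLC6A6 were among the largest falls. ASNS, on chromosome 7 from 97852118 to 97872542, went from 2.08 ± 0.546 to 5.21 ± 0.288 CPM (mean ± SD, n = 3), a log2 change of 1.34 ± 0.20; in GENCODE release 29 another gene on the same strand shares 44.6% of its exon bases, so its level is uncertain. PSAT1, an enzyme of serine synthesis, rose by 1.15 ± 0.052. SLC5A3, the myo-inositol transporter on chromosome 21 from 34073570 to 34106262, fell from 363 ± 10.2 to 146 ± 3.36 CPM (-1.31 ± 0.042), and SLC6A6, the taurine transporter, fell by 1.21 ± 0.059.

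In the ATF4 and amino acid response list 25 of 34 tested members rose and 2 fell (27 and 2 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 1.21e-19). ATF4 rose by 0.71 ± 0.037, the cystine transporter SLC7A11 by 0.91 ± 0.052, PCK2, mitochondrial PEP carboxykinase, by 0.90 ± 0.055 and CHAC1 by 1.23 ± 0.11. Of the aminoacyl-tRNA synthetases 12 of 20 rose and 1 fell (12 and 3 adjusted over the list alone; camera adjusted p = 5.91e-08), with GARS1 at 0.88 ± 0.039 and YARS1 at 0.68 ± 0.040. Of the cytosolic ribosomal proteins 24 of 40 rose (28 adjusted over the list alone; camera adjusted p = 4.98e-08, but adjusted p = 0.118 with an estimated correlation), with RPL3 at 0.23 ± 0.035. Of the p53 targets 12 of 23 rose (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.59e-07), with GADD45A at 0.60 ± 0.043 and the p53 ubiquitin ligase MDM2 at 0.37 ± 0.043. HMOX1 rose by 0.44 ± 0.065, and the NRF2 targets were not called as a list (camera adjusted p = 0.487): 3 of 30 rose and 5 fell (4 and 6 adjusted over the list alone).

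Of the hypoxia and glycolysis genes 1 of 23 tested members rose and 18 fell (1 and 18 adjusted over the list alone; camera adjusted p = 6.17e-13), with BNIP3 at -0.66 ± 0.039 and LDHA at -0.58 ± 0.035. Of the endoplasmic reticulum chaperones 1 of 23 rose and 15 fell (1 and 19 adjusted over the list alone; camera adjusted p = 1.47e-09). HSPA5 fell by 0.83 ± 0.034, the lectin chaperone CALR by 0.42 ± 0.034 and MANF, a stress-inducible secreted factor, by 0.62 ± 0.056. Of the heat shock genes 11 of 20 fell (15 adjusted over the list alone; camera adjusted p = 2.85e-07), with HSPH1, an HSP110 chaperone, at -0.35 ± 0.036 and HSPB1 at -0.31 ± 0.039. Of the interferon response genes 1 of 21 rose and 12 fell (1 and 12 adjusted over the list alone; camera adjusted p = 1.57e-05), with OASL at -0.51 ± 0.038. Of the fibroblast markers 5 of 8 fell (5 adjusted over the list alone; camera adjusted p = 0.000765), with the growth factor receptor PDGFRB at -0.63 ± 0.070. Of the mitosis genes 11 of 23 fell (11 adjusted over the list alone; camera adjusted p = 0.000675, but adjusted p = 0.157 with an estimated correlation), with the proliferation marker MKI67 at -0.27 ± 0.035. The list of asparagine, aspartate and glutamine metabolism was not called (camera adjusted p = 0.354): 8 of 23 rose and 4 fell (8 and 4 adjusted over the list alone), with the amino acid transporter SLC38A2 at -0.47 ± 0.040.

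Other large rises were those of ZMAT1 (1.56 ± 0.16), ULBP1, a ligand of natural killer cells (1.34 ± 0.12), SULT1C2 (1.26 ± 0.14) and PTPRG-AS1 (1.29 ± 0.23), an antisense gene whose reads cannot be told from those of its partner if strand was not used in counting. Other large falls were those of PRSS35 (-2.81 ± 0.25), the cytokine IL11 (-1.48 ± 0.058) and PECAM1, an adhesion molecule (-1.34 ± 0.23). Across all genes edgeR called 3612 in NC-A against NC, 1668 higher and 1944 lower, 192 of them by at least 2-fold. Without NC-A 1, the library that stands apart, 2982 genes were called. Camera called 12 lists, of which 9 were also called with an estimated correlation.

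DHN-A against NC-A asked what 1,2-DHN did in cells given asparagine. Heat shock genes were among the largest rises, and hypoxia and glycolysis genes among the largest falls. HSPA6 went from 3.34 ± 0.20 to 11.4 ± 1.23 CPM (mean ± SD, n = 3), a log2 change of 1.77 ± 0.11. ARC rose by 2.15 ± 0.19, HSPA1A by 2.09 ± 0.18 and CRYAB by 1.81 ± 0.24, while BNIP3 fell by 0.88 ± 0.040 and LDHA by 0.63 ± 0.035. HMOX1 was not called (log2 change 0.13 ± 0.061, edgeR adjusted p = 0.338).

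Of the hypoxia and glycolysis genes 17 of 23 tested members fell (18 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 9.83e-29); PDK1, which restrains pyruvate oxidation, was at -0.90 ± 0.088 and HK2, hexokinase, at -0.65 ± 0.045. Of the NRF2 targets 5 of 30 rose (7 adjusted over the list alone; camera adjusted p = 3.3e-07), with NQO1 at 0.41 ± 0.050 and FTH1, the ferritin heavy chain, at 0.35 ± 0.041. Of the aryl hydrocarbon receptor targets 4 of 7 rose (5 adjusted over the list alone; camera adjusted p = 1.4e-07), with AHRR, the repressor of that receptor, at 0.28 ± 0.049. Of the NF-kappaB and inflammatory genes 7 of 21 rose (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.92e-09), with the cytokines IL1B at 0.28 ± 0.039 and CXCL8 at 0.24 ± 0.037. Of the heat shock genes 5 of 20 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00435, but adjusted p = 0.114 with an estimated correlation). Of the cytosolic ribosomal proteins 15 of 40 fell (27 adjusted over the list alone; camera adjusted p = 5.01e-17, and 0.0269 with an estimated correlation), with RPS24 at -0.28 ± 0.036. Camera had called that list higher in the same NC-A libraries against NC. In DHN-A against NC it was not called (camera adjusted p = 0.954, median 0.0081). Of the aminoacyl-tRNA synthetases 5 of 20 fell (9 adjusted over the list alone; camera adjusted p = 3.3e-07), with GARS1 at -0.19 ± 0.038. Other large changes were those of PPFIA4 (-1.13 ± 0.13), CA9 (-0.77 ± 0.15) and APLN (-0.76 ± 0.12). CYP4F11, a cytochrome P450, was at 0.85 ± 0.23 (edgeR adjusted p = 0.0335); its call was lost without NC-A 1 (0.0553), NC-A 3 (0.307), DHN-A 2 (0.211) or DHN-A 3 (0.119), and with limma-voom (0.0627), in a range of 0.0173 to 0.307 over 14 alternatives.

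Across all genes edgeR called 375 in DHN-A against NC-A, 144 higher and 231 lower, and 10 of them changed at least 2-fold. The count was 143 without DHN-A 2, 170 without NC-A 3, 226 without NC-A 2 and 230 without DHN-A 1, and 288 without NC-A 1, which stands apart. The balance of direction turned with no filter on low counts (271 higher and 127 lower) and was 77 and 285 after removal of a GC trend. Camera called 14 lists, of which 9 were also called with an estimated correlation.

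DHN-A against NC asked how cells given both differed from cells given neither. Hypoxia and glycolysis genes and endoplasmic reticulum chaperones were lower, and amino acid response genes higher. BNIP3, on chromosome 10 from 131966455 to 131982013, went from 330 ± 2.53 to 113 ± 1.13 CPM (mean ± SD, n = 3), a fall of 1.54 ± 0.039, and LDHA fell by 1.22 ± 0.035. HSPA5 fell by 0.99 ± 0.034, while PSAT1 rose by 0.90 ± 0.050 and SLC7A11 by 0.90 ± 0.050. HMOX1 was higher by 0.57 ± 0.060 and NQO1 by 0.52 ± 0.049.

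Of the hypoxia and glycolysis genes 1 of 23 tested members rose and 20 fell (1 and 20 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 5.54e-24). Of the endoplasmic reticulum chaperones 1 of 23 rose and 18 fell (1 and 20 adjusted over the list alone; camera adjusted p = 5.19e-13), and in the ATF4 and amino acid response list 26 of 34 rose and 5 fell (27 and 5 adjusted over the list alone; camera adjusted p = 6.27e-16). Of the mitosis genes 17 of 23 fell (18 adjusted over the list alone; camera adjusted p = 1.11e-09), and of the interferon response genes 1 of 21 rose and 12 fell (1 and 14 adjusted over the list alone; camera adjusted p = 2.07e-09). Of the fibroblast markers 5 of 8 fell (5 adjusted over the list alone; camera adjusted p = 0.000219, and 0.0227 with an estimated correlation). The NRF2 targets were not called as a list (camera adjusted p = 0.0627): 10 of 30 rose and 4 fell (10 and 4 adjusted over the list alone). Of the heat shock genes 2 of 20 rose and 9 fell (2 and 9 adjusted over the list alone). Camera called that list lower (adjusted p = 0.000488, but adjusted p = 0.0577 with an estimated correlation) with a median of -0.089, whereas its mean was 0.059: HSPA1A (1.61 ± 0.15) and CRYAB (2.39 ± 0.24) rose and others, such as HSPH1 (-0.33 ± 0.036), fell. ARC (2.53 ± 0.18), ZMAT1 (1.46 ± 0.16) and HSPA6 (1.40 ± 0.10) were also among the largest rises, and PRSS35 (-2.39 ± 0.21), PPFIA4 (-2.08 ± 0.12) and CA9 (-1.74 ± 0.14) among the largest falls. The symbols BNIP3P1 (-1.96 ± 0.47) and RPL7P9 (-1.86 ± 0.28) name pseudogenes, whose reads can come from their parent genes. The call of BNIP3P1 (edgeR adjusted p = 0.0182) was lost without NC 1 (0.0551), NC 3 (0.0562), DHN-A 1 (0.0676) or DHN-A 2 (0.0637), in a range of 4.2e-08 to 0.0676 over 15 alternatives.

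Across all genes edgeR called 3769 in DHN-A against NC, 1758 higher and 2011 lower, 240 of them by at least 2-fold; with NC-A 1 out of the shared fit it called 4059. Camera called 16 lists, of which 11 were also called with an estimated correlation. Of the 6919 genes called in DHN against NC, 4749 (68.6%) were not called here, which does not show that they equal NC. Against the same NC libraries, DHN-A and NC-A shared 1093 genes called higher (164 if independent) and 1282 called lower (219 if independent). The simulated overlaps (means of 0.050 and 0.10) are near 0 by construction, since the groups had no change, and do not measure what shared libraries add. Across genes the changes of DHN-A and NC-A had r = 0.730 (simulated 0.491) and a covariance of 0.113 (simulated 0.0328, a difference of 0.0801), and part of the excess overlap may come from the shared libraries.

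The interaction asked whether the effect of 1,2-DHN differed with asparagine; a negative value means a lower log2 change with it. Heat shock and NRF2 genes had negative values: HSPA6 was at -5.09 ± 0.18, HSPA1A at -2.97 ± 0.28 and HMOX1 at -1.95 ± 0.084 (log2 ± SE, 3 libraries in each of 4 groups). Amino acid response genes were also negative: ASNS and ATF4, which each treatment raised alone, were at -1.40 ± 0.26 and -0.78 ± 0.051, and SLC3A2 was at -1.48 ± 0.057. Interferon and mitosis genes were positive, with MX1 at 1.22 ± 0.060 and PLK1 at 0.72 ± 0.062, and the death ligand TNFSF10 was at 1.68 ± 0.11.

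Of the heat shock genes 20 of 20 were called lower (20 adjusted over the list alone; camera adjusted p = 1.8e-22), and of the NRF2 targets 19 of 30 (21 adjusted over the list alone; camera adjusted p = 6.74e-12). In the ATF4 and amino acid response list 23 of 34 were lower and 1 higher (24 and 1 adjusted over the list alone; camera adjusted p = 3e-13). Of the interferon genes 17 of 21 were called higher (17 adjusted over the list alone; camera adjusted p = 7.67e-13), and of the mitosis genes 17 of 23 (18 adjusted over the list alone; camera adjusted p = 7.09e-11). Of the fibroblast markers 6 of 8 were called higher (6 adjusted over the list alone; camera adjusted p = 0.00011). Across all genes edgeR called 4592, 2361 higher and 2231 lower, 378 of them by at least 2-fold; without NC-A 1 it called 4420. Camera called 18 lists, of which 12 were also called with an estimated correlation.

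**Figure D3:**
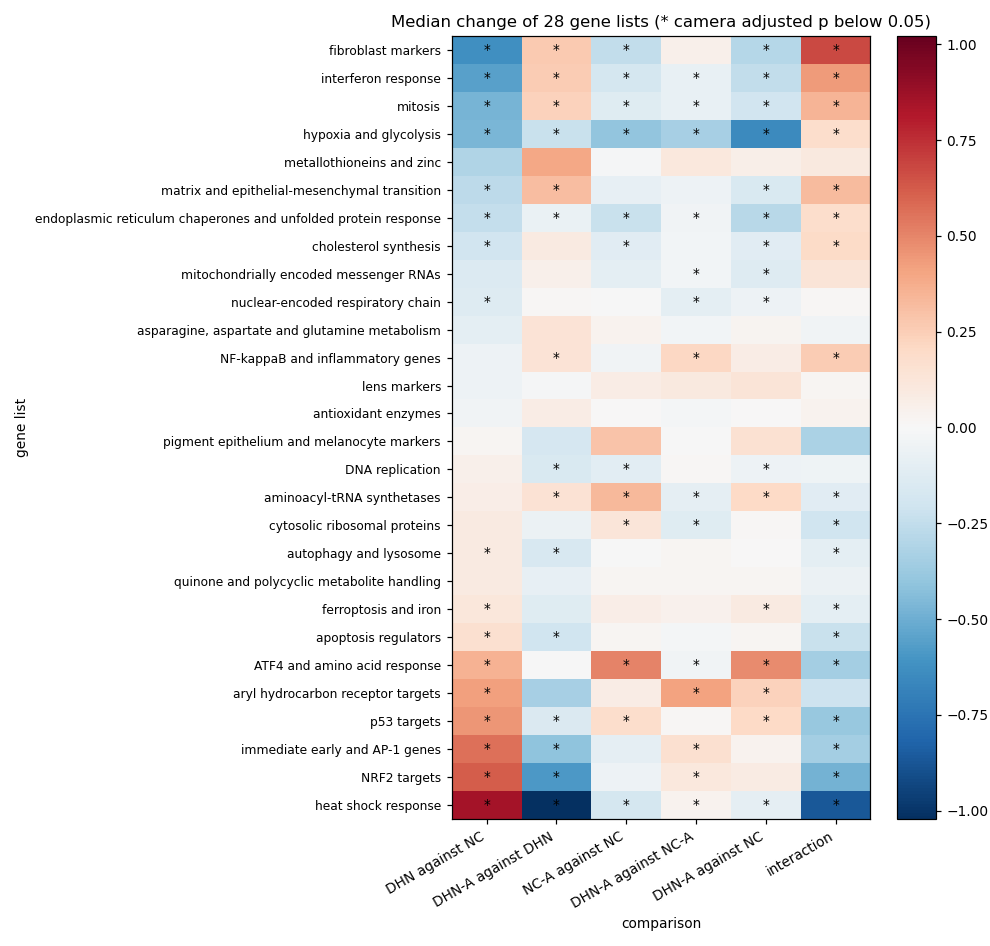
Median log2 fold change of the tested members of 28 gene lists (lines) in the 6 comparisons (columns), with an asterisk where the camera adjusted p is below 0.05. The heat shock list has the highest median in DHN against NC (0.85) and the lowest in DHN-A against DHN (-1.02).

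Set against each other over all tested genes, the log2 changes of DHN-A against NC-A had a total least squares slope of 0.137 (jackknife SE 0.0463) on those of DHN against NC. These comparisons share no library. The slope was 0.217 without NC-A 2 and 0.242 without NC-A 3, and 0.119 over the genes called in DHN against NC. The correlation across genes, which are not independent replicates, was 0.173. Both comparisons called 83 genes higher, where independent lists would share 28, and 146 lower, where they would share 44. The 2 comparisons share each gene's estimate of spread, which the independent overlaps leave out, so part of the excess may come from it.

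**Figure D4:**
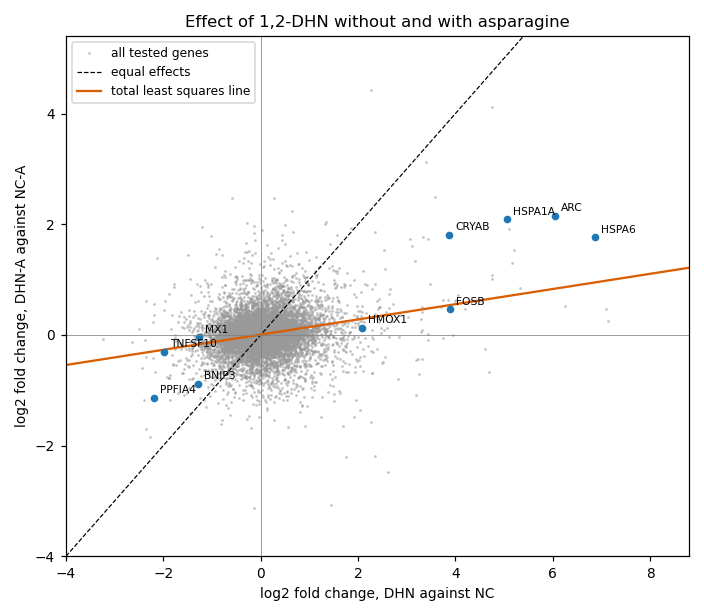
Log2 fold change of each of 17889 tested genes in DHN against NC (horizontal axis) and in DHN-A against NC-A (vertical axis), with the line of equal effects (dashed) and the total least squares line (slope 0.137); 1 gene lies outside the axes. HSPA6 lies at 6.86 and 1.77, below the line of equal effects.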

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

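The tests of whether DHN-A received any 1,2-DHN and of a single scaling factor were chosen only after the result was seen. The effect of 1,2-DHN differed with and without asparagine in a test of that difference, the interaction of edgeR's model, for 4592 genes and, by camera, for 18 lists. Of 100 splits of the 12 libraries into 4 groups of 3, 1 (the real one) called as many genes and 1 as many lists, and the highest other split called 3757 genes and 16 lists. This excludes chance for libraries without any treatment effect, but such splits mix the effects of both treatments into the interaction, so they do not test treatment effects without an interaction. Lists with a lower log2 change from 1,2-DHN under asparagine, by median log2 interaction, were heat shock (-0.86), NRF2 targets (-0.48), p53 targets (-0.39), ATF4 and amino acid response (-0.35), immediate early and AP-1 genes (-0.35), apoptosis regulators (-0.22), ribosomal proteins (-0.20), aminoacyl-tRNA synthetases (-0.12), ferroptosis and iron (-0.10) and autophagy (-0.10). Lists with a higher log2 change were hypoxia and glycolysis (0.18), endoplasmic reticulum chaperones (0.18), cholesterol synthesis (0.20), NF-kappaB (0.26), matrix (0.32), mitosis (0.34), interferon (0.43) and fibroblast markers (0.68). Higher does not mean stronger here. In that order, the medians in DHN against NC were -0.47, -0.24, -0.19, -0.050, -0.27, -0.48, -0.55 and -0.62. In DHN-A against NC-A they were -0.34, -0.0375, -0.029, 0.21, -0.051, -0.075, -0.076 and 0.054. These falls were thus smaller with asparagine or turned to a rise. With an estimated correlation 6 of the 18 lists were not called: AP-1 (adjusted p = 0.091), ribosomal proteins (0.0942), aminoacyl-tRNA synthetases (0.091), autophagy (0.0729), hypoxia (0.158) and endoplasmic reticulum chaperones (0.181). The autophagy call (camera adjusted p = 0.0363) was also lost without NC 1 (0.0533), NC-A 1 (0.0592) or DHN-A 1 (0.0753), in a range of 2.27e-05 to 0.0753 over 16 alternatives.

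Among single genes the log2 interaction was -5.09 ± 0.18 for HSPA6, -3.90 ± 0.32 for ARC, -3.74 ± 0.29 for RASD1, -3.43 ± 0.25 for FOSB and -2.97 ± 0.28 for HSPA1A. It was -1.95 ± 0.084 for HMOX1, -1.78 ± 0.15 for ADM, -1.64 ± 0.14 for CHAC1, -1.48 ± 0.057 for SLC3A2, -1.40 ± 0.26 for ASNS, -1.35 ± 0.052 for BAG3 and -0.78 ± 0.051 for ATF4. Positive values were 0.39 ± 0.048 for HSPA5, 0.72 ± 0.062 for PLK1, 1.22 ± 0.060 for MX1, 1.33 ± 0.11 for IL4I1, 1.37 ± 0.061 for TENM2, 1.45 ± 0.26 for IDO1, 1.47 ± 0.076 for GBP4 and 1.68 ± 0.11 for TNFSF10.

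For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real one was the 1 split with the most calls in each. DHN against NC called 6919 genes (highest other split 0) and 17 lists (12), DHN-A against DHN 7455 genes (0) and 15 lists (6), and NC-A against NC 3612 genes (0) and 12 lists (8). DHN-A against NC-A called 375 genes (5) and 14 lists (7), and DHN-A against NC 3769 genes (0) and 16 lists (11).

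Fewer genes were called in DHN-A against NC-A (375) than in DHN against NC (6919). Spread added by NC-A 1 is argued against as the whole cause, since 288 genes were called without that library. That the DHN-A libraries received no 1,2-DHN is argued against too: of the 20 genes with the largest called rises in DHN against NC, 3 (HSPA6, ARC and HSPA1A) also rose by at least 1 on the log2 scale in DHN-A against NC-A. The 20 were taken from all tested genes, without the criteria of the naming rule, and did not include CRYAB. A single factor that scales the whole response down left at least 262 genes departing from it at each of 21 factors from 0 to 1 (fewest at 0.1); an earlier test of the same idea had left it open, with slopes of 0.312 for heat shock and 0.411 for hypoxia genes and a difference of 0.0984 ± 0.0632 (jackknife SE). An effect of asparagine on the cells' response, and a lower effective exposure to 1,2-DHN with genes that differ in dose response, may both account for the pattern and were not tested apart.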

How the results depend on the processing

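Thinning to 1 depth, removal of a GC trend, protein-coding genes alone and the fit without NC-A 1 were chosen after the data were seen. In the 6 counts of called genes, relative log expression factors, DESeq2, limma-voom, no filter, the fit of only the groups compared (not run for the interaction) and those added settings stayed within 1.5 times of the reported value. Relative log expression factors moved the median of all genes by -0.00826 in NC-A against NC and by less in the others. A minimum of 2-fold left 635, 670, 192, 10, 240 and 378 genes (DHN against NC, DHN-A against DHN, NC-A against NC, DHN-A against NC-A, DHN-A against NC, interaction), by its own construction. Leaving out 1 library gave 6126 to 6428, 6575 to 6947, 2773 to 3261, 143 to 356, 2782 to 3225 and 4051 to 4503 genes in the same order. Counts lower by more than 1.5 times, all in DHN-A against NC-A, were 143 without DHN-A 2, 170 without NC-A 3, 226 without NC-A 2 and 230 without DHN-A 1. Lists called stayed within 17 to 18, 13 to 16, 12 to 13, 13 to 16, 15 to 17 and 17 to 19. An estimated correlation left 3 lists in DHN-A against DHN and 9 in DHN-A against NC-A, and fry, which does not compare a list with other genes, called 23 in DHN-A against DHN. The slope of the 1,2-DHN effect with asparagine on that without ranged from 0.108 to 0.242 (0.217 without NC-A 2, 0.242 without NC-A 3), the covariance of the asparagine and 1,2-DHN effects from -0.250 to -0.218, and the share of opposite signs from 92.2% to 93.8%; the cause was not tested for the slope. Fits without a library keep more genes with few counts, since the filter follows the smallest group. With no filter the covariance was -1.04 and the share 94.1%; the cause was not tested. With no filter the calls higher and lower were 271 and 127 in DHN-A against NC-A, 1044 and 2143 in NC-A against NC and 2616 and 1545 in the interaction, and with the GC trend removed 77 and 285 in DHN-A against NC-A (144 and 231, 1668 and 1944, and 2361 and 2231 as reported).

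Of the named genes, 2907 values kept direction and side of the threshold, 9 were weaker, 1 stronger and 6 reversed; over relative log expression factors, the replicate block, an estimated correlation, fry and each library left out, the alternatives run for lists, 974 list calls held and 54 were lost. Signs turned for AKR1B1, DHN against NC (-0.0232 to 0.0353 leaving out 1 library, 0.0033 without NC 3 and 0.0353 without DHN 2; 0.0027 thinned; 0.0026 in protein-coding genes) and for ASNS, DHN-A against DHN (-0.160 to 0.0012, the last without DHN-A 1; 0.0289 thinned), neither of which was called; the cause was not tested. In DHN-A against DHN list calls were lost for NF-kappaB without DHN 1 (0.0567) or DHN-A 2 (0.0552), for fibroblast markers without DHN 2 (0.0564) or DHN-A 3 (0.0682), for apoptosis without DHN-A 1 (0.0521) or DHN-A 3 (0.0547) and for autophagy without DHN-A 1 (0.0521); over 10 alternatives each the adjusted p ranged from 6.73e-05 to 0.125, 1.48e-06 to 0.129, 9.02e-07 to 0.0853 and 5.08e-07 to 0.0757. In DHN-A against NC that of ferroptosis was lost without NC 2 (0.0517) or DHN-A 3 (0.0707; range 1.67e-05 to 0.0831), and in DHN-A against NC-A that of mitochondrial messenger RNAs without NC-A 1 (0.0583), NC-A 2 (0.0554) or DHN-A 3 (0.663) and with fry (0.389; range 0.00116 to 0.663). Thinned to the shallowest library, DHN against NC called 6318 genes; of its reported calls, thinning lost 27.2% of the 1730 with mean counts up to 297.5 and 3.18% of the 1730 with mean counts from 1878.

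The replicate numbers do not pair the libraries: over 18 pairs with the same number the deviations from the group means correlated by -0.176 to 0.229 (1 pair over 0.1), and 5 of 12 libraries correlated best with their own number. With the replicate number as a block the calls were 6805, 7361, 3458, 334, 3585 and 4477 genes in the order above, and the calls of fibroblast markers in DHN-A against DHN (0.0621) and ferroptosis in DHN-A against NC (0.0525) were lost.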

Other observations

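The tests on pseudogenes, on shared exons and of NC-A 1 against the other groups were chosen only after the result was seen. Some iron and cholesterol genes changed with 1,2-DHN. TFRC, the transferrin receptor for iron uptake, fell by 1.00 ± 0.039 (log2 ± SE, n = 3 per group) in DHN against NC and by 0.61 ± 0.038 in DHN-A against NC-A. Of the ferroptosis and iron genes 10 of 19 rose and 4 fell (11 and 4 adjusted over the list alone) in DHN against NC (camera adjusted p = 0.0111). HMOX1, FTH1, FTL and SLC7A11 of this list are also NRF2 targets. SLC7A11, SLC3A2 and CHAC1 are also in the ATF4 and amino acid response list. The list's median log2 change of 0.115 lay below its mean of 0.357. Of the cholesterol synthesis genes 1 of 22 rose and 13 fell (2 and 13 adjusted over the list alone) in DHN against NC (camera adjusted p = 0.000135), with LSS, lanosterol synthase, at -0.66 ± 0.051. In NC-A against NC 7 of 22 fell (7 adjusted over the list alone, camera adjusted p = 0.000351). Neither list was called in DHN-A against NC-A. There, of the ferroptosis and iron genes 2 of 19 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.403). Of the cholesterol synthesis genes 0 of 22 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.194).

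Replication genes did not follow mitosis genes in DHN against NC, where 11 of 25 rose and 5 fell (11 and 5 adjusted over the list alone) and the list was not called (camera adjusted p = 0.0989); CDC6, a replication licensing factor, rose by 0.75 ± 0.050. In DHN-A against DHN 1 of 25 rose and 12 fell (1 and 15 adjusted over the list alone; camera adjusted p = 0.00181, but adjusted p = 0.0757 with an estimated correlation), and CDC6 fell by 0.99 ± 0.049. In NC-A against NC 11 of 25 fell (1 higher and 13 lower adjusted over the list alone; camera adjusted p = 0.00952, but adjusted p = 0.118 with an estimated correlation), with FEN1, a flap endonuclease, at -0.30 ± 0.045. The cytokine IL11 fell by 1.43 ± 0.054 in DHN-A against DHN and by 1.48 ± 0.058 in NC-A against NC.

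NC-A 1 lay apart from the other libraries over all tested genes. Its deviation from NC-A 2 and NC-A 3 had an SD of 0.662 (log2), and that of no library of the other groups was above 0.379. It did not by the mean chi-square per gene, which leaves out genes with few counts and grows with depth. That was 3.74 with NC-A 2 and 4.30 with NC-A 3, where the highest pair, DHN-A 2 with DHN-A 3, had 4.98. GC content and gene length together explained 0.394% of the variance of that deviation over protein-coding genes, which argues against them as its cause in those genes. They were not tested over the other genes, which the SD of 0.662 includes. Shallow sequencing as the whole cause is argued against by thinning, which makes depth equal and still left the SD 1.504 times that of the next library (1.49 to 1.51 over 10 draws, so a bound of 1.5 set beforehand was met in only some draws); that library, NC-A 3, is itself measured against NC-A 1, and the ratio to the highest library of the other groups was 1.82 (1.79 to 1.83 over the draws). Reads placed differently between genes and pseudogenes may contribute: the median deviation of 1618 pseudogenes lay -0.461 from that of 13310 protein-coding genes, between the bounds set for either answer. The pseudogene medians ran from -0.268 to 0.230 in the other groups and were 0.291 in NC-A 2 and 0.340 in NC-A 3, which are measured against NC-A 1, and no biological explanation was tested.

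ASNS had few counts, 2.08 ± 0.546 CPM in NC. A candidate explanation is that reads in exons shared with another gene on the same strand were not counted: of 438 protein-coding genes with at least 90% of their exon bases shared in GENCODE release 29, 1.37% reached 1 CPM, against 64.8% of 17716 genes that share under 10%. ASNS shares 44.6%, so part of its exons would still be counted, and a low level of its messenger RNA in these cells stays open.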
